A study of Homo sapiens with 16 samples.

How the data were processed

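RNA-seq was deposited for Jurkat E6-1 cells, an established human T cell line whose disease the labels give as lymphoma. Per the labels, 8 libraries came from untreated cells at the start (0 h) and 8 from cells that were suspended in phosphate-buffered saline, given 10 µM hydrogen peroxide and collected after 4 h. The labels call the libraries biological replicates. A group of untreated cells kept in saline for 4 h was not analysed here, so time, the change of medium and peroxide differ together between the groups. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with an Illumina TruSeq kit. The names under which the tables were deposited split the libraries into 2 batches, with 4 libraries of each group in each; what a batch stands for is not given in the sources used here.

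The deposited values are whole-number read counts per gene, 1 table per library, with no normalization. Per the submitters' processing notes, STAR 2.7.1a and HTSeq 0.6.1 were used and hg19 was the genome build. The 60662 gene identifiers carry version numbers, and 68.0% of them matched GENCODE release 29, an annotation of GRCh38, to the version. The build was therefore left open and no coordinates are printed. The counting mode and the use of strand are not given in the sources used here. Gene symbols came from a table of gene identifiers, which matched 60402 identifiers (99.6%). Each table also has 5 rows that name no gene, which held 43.5% to 57.6% of the counted reads. Reads not aligned uniquely made up most of these, and the rows were kept out of library sizes and tests. A read that fits several near-identical genes is not counted for any of them, so levels of ribosomal protein genes, histones, metallothioneins, HSPA1A and HSPA1B, and mitochondrial genes with nuclear copies are uncertain. Reads of overlapping or antisense genes cannot be told apart without knowledge of the strand setting.

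Reads in genes ranged from 5556553 to 15720881 per library. Genes were kept with edgeR's filterByExpr (version 4.0.16, R 4.3.3), which left 14092 genes holding 99.6% of the reads in genes. The filter was run on the groups, so a gene scarce in controls could pass through the treated libraries alone, and the reverse. Counts were scaled with TMM factors and tested with edgeR's quasi-likelihood test, with batch and group as terms. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. A log2 fold change of 1 or more in size was called 2-fold. Standard errors (SE) of log2 fold changes were the size of the fold change divided by the square root of the test's F value. Levels are counts scaled to library size as CPM with TMM scaling, given as mean ± SD over 8 libraries. The batch was tested as a modifier with the interaction of batch and group. Lists of genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, and again with an estimated correlation. At the preset correlation, lists were also called in random splits of the libraries where 0 genes were called. List calls made only at that setting are therefore less certain. The 42 lists were fixed before the data were examined, and 38 had the 5 tested members that the test required. A called list and a few genes that the naming rule took are not reported here. Counts of list members "adjusted over the list alone" use Benjamini-Hochberg adjustment within the list. Library measures were compared with exact permutation tests, two-sided.

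The genes named were taken by a rule fixed before the data were examined. It took the 15 largest rises and the 15 largest falls among called genes with a mean of 5 CPM or more, a symbol that is not a clone name and the same sign in both batches. It also took up to 4 members with the smallest p and a mean of 1 CPM or more from each list described, 20 fixed examples, and the 5 genes with the smallest interaction p at a mean of 5 CPM or more. Genes outside this rule are marked where they appear, except that the few list members moving against or apart from the rest, named beside a count (such as ID3, EDEM1, GPX4 and MALT1), were also chosen after their values were seen.

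No libraries of a group agreed within sampling noise. The chi-square statistic per degree of freedom was 2.96 to 18.2 for pairs within a batch and 23.7 to 41.6 for libraries that carry the same number in both batches, so all 16 libraries were kept as separate replicates. On simulated counts for 14092 genes in the design of 8 against 8, the test recovered 52.0% of genes changed 1.25-fold, 92.0% at 1.5-fold and 100% at 2-fold and at 4-fold, and 10 of 205 calls were false. For the interaction, it recovered 4.00%, 28.0%, 80.0% and 100% at these sizes, with 2 of 108 calls false. At each size 50 genes were changed, all with a mean of 5 CPM or more. Far more genes were called in the real data, so these rates do not cover genes at lower levels or a response that wide.

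Alternatives were DESeq2 (version 1.42.0), limma-voom, other scaling factors or none, other filters, leaving out mitochondrially encoded genes, no batch term, the replicate number as a block, each batch alone, summing libraries of the same number across batches, and leaving out each library. Neighbouring genes were taken from GENCODE release 29, for order, strand and distance only; since the build of the counts is open, no distance of a single pair is printed.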

Results

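Gene expression was measured by RNA-seq in Jurkat E6-1 cells, a T cell line, before treatment and 4 h after transfer to saline with 10 µM hydrogen peroxide. The comparison asked which genes differ between treated and untreated cells. Each group had 8 libraries, 4 in each of 2 batches, with 5556553 to 15720881 reads in genes per library. The peroxide group also differed from the control by 4 h of incubation in saline, and every difference below includes that step. The share of counted reads not aligned uniquely was 34.1% ± 5.43 in controls and 38.3% ± 4.33 after peroxide (SD, n = 8 each; exact permutation p = 0.107, two-sided, Benjamini-Hochberg adjusted 0.163 over the library measures). In batch 2 alone it was 32.8% ± 0.942 and 40.8% ± 4.46 (exact permutation p = 0.0286, the smallest possible with n = 4 each), and in batch 1 alone 35.3% ± 7.98 and 35.9% ± 2.83 (exact permutation p = 0.943).

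Peroxide-treated cells had more JUN and HSPA5 transcripts and fewer MT-ND6 transcripts than controls. JUN (ENSG00000177606.7), a subunit of the AP-1 transcription factor, went from 36.3 ± 22.6 CPM in controls to 1397 ± 250 CPM (SD, n = 8 each). HSPA5 (ENSG00000044574.8), the main chaperone of the endoplasmic reticulum (ER), went from 294.1 ± 200 to 4288 ± 1442 CPM. MT-ND6 (ENSG00000198695.2), a mitochondrially encoded subunit of respiratory complex I, fell from 601.6 ± 144 to 70.98 ± 14.8 CPM. In all 3 genes every treated library lay outside the range of the 8 controls. Of 14092 genes tested, 3391 were higher and 3419 lower after peroxide with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. Changes of at least 2-fold were mostly rises, with 836 genes higher and 129 lower. With total counts in place of TMM factors the split was 2822 higher and 4375 lower. The first principal component (47.8% of variance) separated the treatments and the second (29.5%) the batches.

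**Figure D1:**
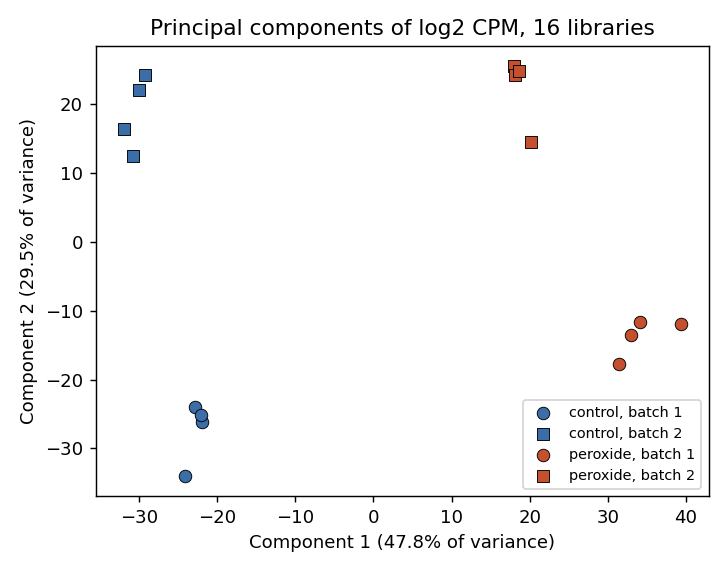
Principal components 1 (horizontal) and 2 (vertical) of log2 CPM over 11093 genes, 1 point per library, colour for group and marker shape for batch. Component 1 holds 47.8% of the variance and parts the 8 control from the 8 peroxide libraries, and component 2 holds 29.5% and parts the batches.

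Several of the largest rises were in genes with low control levels. IQCN (ENSG00000130518.17) went from 1.73 ± 0.659 to 194.1 ± 58.6 CPM, a log2 fold change of 6.68 ± 0.22 (SE). CRISPLD2, ARC and SNAI1 had log2 fold changes of 6.50, 5.36 and 5.33. SNAI1 is a transcription factor and ARC is an activity-induced gene of neurons. RHOB, DUSP8, ADAMTSL4, VASN, TUBB3, KLF4, NR4A3 and SERTAD1 rose by 4.11 to 5.32 on the log2 scale. CRISPLD2 had a mean of 0.132 CPM in controls, so its fold change rests on few control reads. Adjusted p-values of the 15 largest rises were at most 8.49e-10 (edgeR quasi-likelihood test, Benjamini-Hochberg), and all 8 treated libraries lay above all controls for each.

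Immediate early genes, which are transcribed within minutes of a stimulus, had the largest median change of the 38 lists tested with camera. Of 31 tested members 25 rose and 2, MYC and ID3, fell, over all genes and adjusted over the list alone, with a median log2 fold change of 2.02. JUND rose by 3.05 ± 0.15, FOSL2 by 2.19 ± 0.12, NR4A3 by 4.24 ± 0.21 and FOS by 2.95 ± 0.46 on the log2 scale. EGR1 stood at 1.21 ± 0.46 (adjusted p = 0.0336, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and lost its call without control 1, 4 or 5 or peroxide 4 or 8 (edgeR, Benjamini-Hochberg adjusted p 0.0505 to 0.0725), with DESeq2, without a batch term, with summed libraries, in batch 2 alone and without the 2 libraries with most reads not aligned uniquely. The list was higher by camera (Benjamini-Hochberg adjusted p = 4.28e-17; adjusted p = 0.151 with an estimated correlation). Feedback inhibitors of MAP kinase signalling rose as well, 14 of 20 with DUSP2 and SPRY1 lower, and 15 higher and 2 lower adjusted over the list alone. DUSP8 (4.94 ± 0.24), SPRY4 (3.94 ± 0.21), GADD45B (3.57 ± 0.24) and PHLDA1 (2.68 ± 0.14) had the smallest p-values, and DUSP1 rose by 2.20 ± 0.15. This list passed camera both ways (Benjamini-Hochberg adjusted p = 4.94e-11; adjusted p = 0.0160 with an estimated correlation).

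ER chaperones rose almost as a block, with 18 of 19 tested members higher and 1, EDEM1, lower, over all genes and adjusted over the list alone. HSPA5 rose by 4.16 ± 0.32, HERPUD1, a factor of ER-associated degradation, by 3.73 ± 0.19, DNAJB9 by 3.04 ± 0.16 and DNAJB11 by 2.10 ± 0.16 on the log2 scale. The share of reads in genes held by this list went from 0.435% to 1.28%. The list was higher by camera (Benjamini-Hochberg adjusted p = 4.20e-11; adjusted p = 0.275 with an estimated correlation). Genes of the ATF4 and amino acid response rose in 22 of 29 cases, and SLC7A1 and AARS1 fell, with the counts adjusted over the list alone at 22 and 2. ATF4 itself went from 499.8 ± 24.9 to 1130 ± 161 CPM, and DDIT3, which encodes the stress factor CHOP, from 20.5 ± 14.6 to 276.5 ± 52.3 CPM. PPP1R15A rose by 3.22 ± 0.20 and SLC38A2, an amino acid transporter, by 1.55 ± 0.13. The list was called by camera (Benjamini-Hochberg adjusted p = 2.89e-07; adjusted p = 0.369 with an estimated correlation). Cytosolic heat shock genes rose in 10 of 17 cases with HSPA4L lower (10 and 1 adjusted over the list alone), with the smallest p-values for DNAJB1 (2.04 ± 0.24), DNAJA1 (1.35 ± 0.17), DNAJB4 (1.27 ± 0.16) and DNAJB6 (0.68 ± 0.07). Camera gave a Benjamini-Hochberg adjusted p = 0.00616 for this list, adjusted p = 0.554 with an estimated correlation. Without a batch term the call of the list was lost, and so was that of DNAJA1. HSPA1A, the inducible HSP70, had 28 reads in all controls and 149 in all treated libraries and was below the filter. Its near-identical copy HSPA1B, chosen after its value was seen, rose by 2.72 ± 0.56, and the levels of both are uncertain because reads that fit both are not counted.

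Of 21 tested targets of NRF2, the regulator of the oxidant response, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.35. GCLC and GCLM, the subunits of the enzyme that limits glutathione synthesis, rose by 0.78 ± 0.07 and 0.35 ± 0.09, and TXNRD1, a thioredoxin reductase, by 0.39 ± 0.09. OSGIN1 rose most among the examples, by 2.07 ± 0.21, SQSTM1 rose by 0.85 ± 0.07, and the transporter ABCC1 fell by 0.42. The list was higher by camera (Benjamini-Hochberg adjusted p = 0.000858; adjusted p = 0.275 with an estimated correlation). HMOX1 and SRXN1 were below the filter, with 3 and 79 reads in all controls and 7 and 38 in all treated libraries. Enzymes that remove peroxide and superoxide were not called as a list (adjusted p = 0.854, camera with Benjamini-Hochberg adjustment), with 3 of 20 higher and 2 lower, adjusted over the list alone as well. PRDX6, SOD1 and GPX4 rose by 0.29 ± 0.06, 0.34 ± 0.09 and 0.18 ± 0.07 and MSRB1 and PRDX4 fell by 0.31 and 0.27. GCLM, PRDX6 and SOD1 lost their calls in batch 1 alone, MSRB1 and PRDX4 in batch 2 alone, and TXNRD1, SOD1 and PRDX4 without a batch term. Catalase (CAT) stood at 85.0 ± 11.3 and 80.1 ± 6.69 CPM, a log2 difference of -0.07 ± 0.06 that did not pass. All 4 tested metallothioneins, small metal-binding proteins, rose, with MT1E at 3.43 ± 0.32, MT1X at 2.17 ± 0.15, MT2A at 1.41 ± 0.12 and MT1F at 1.14 ± 0.27. They were too few for a list test and are near-identical in sequence. MT1E was low in most controls and reached the filter through its treated libraries. The MT1E fold depended on the batch. Its controls held 0.183 to 0.415 CPM in batch 1 and 0.751 to 1.81 CPM in batch 2. Its peroxide libraries held 5.65 to 13.1 and 5.53 to 12.2 CPM.

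**Figure D2:**
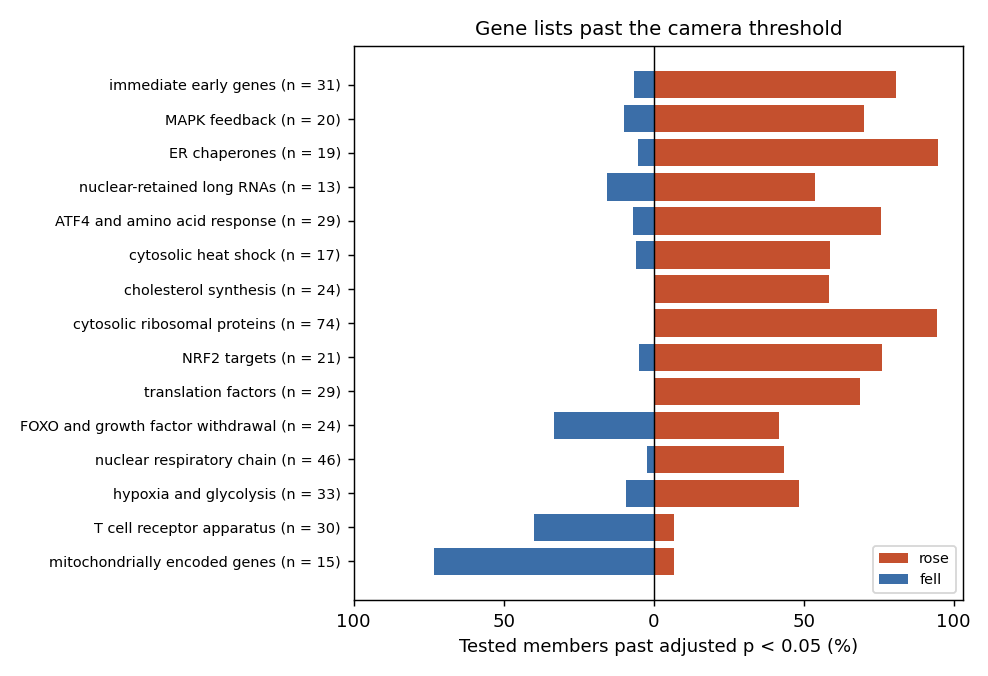
Percent of tested members of each gene list that rose (right) or fell (left) at an adjusted p under 0.05, for 15 of the 16 lists called by camera, ordered by median log2 fold change; n is the number of tested members. Among ER chaperones 18 of 19 rose, and among mitochondrially encoded genes 11 of 15 fell.

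Mitochondrially encoded genes fell, and unevenly. Of 15 tested members 11 fell and 1 rose (11 and 1 adjusted over the list alone), with a median log2 fold change of -0.63. MT-ND6 fell by 3.05, MT-ND5 by 2.32 and MT-CO1 by 1.95 on the log2 scale, and MT-ND4, at 4672 ± 467 CPM the most abundant of the 4, fell by 0.90. MT-ND2 rose by 0.32 ± 0.08, and MT-ATP6 and MT-ATP8 stood at -0.05 ± 0.10 and 0.04 ± 0.12, which did not pass; these 3 genes were chosen after their values were seen. The mitochondrial tRNA genes MT-TY, MT-TL2 and MT-TP fell by 4.02, 3.95 and 2.95. The mitochondrial share of reads in genes was 2.98% ± 0.219 in controls and 1.77% ± 0.304 after peroxide (SD, n = 8 each; exact permutation p = 0.000155, two-sided, the smallest possible here). It fell in each batch alone, from 3.04% ± 0.0756 to 1.69% ± 0.263 and from 2.92% ± 0.312 to 1.85% ± 0.360 (exact permutation p = 0.0286 each, the smallest possible with n = 4). The list was lower by camera (Benjamini-Hochberg adjusted p = 1.00e-08; adjusted p = 0.275 with an estimated correlation). Nuclear genes of the respiratory chain went the other way, with 20 of 46 higher and NDUFS1 lower (19 and 1 adjusted over the list alone). CYCS, which encodes cytochrome c, rose by 0.95 ± 0.06, UQCRB by 0.55 ± 0.06, COX7C by 0.38 ± 0.06 and COX6C by 0.34 ± 0.05. That list's call (camera, Benjamini-Hochberg adjusted p = 0.0299; adjusted p = 0.735 with an estimated correlation) was lost with total-count scaling, without a batch term, with summed libraries, in batch 1 alone and without the 2 libraries with most reads not aligned uniquely. It was also lost without control 5, 6, 7 or 8 or peroxide 5 or 8 (camera, Benjamini-Hochberg adjusted p 0.0582 to 0.0859).

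**Figure D3:**
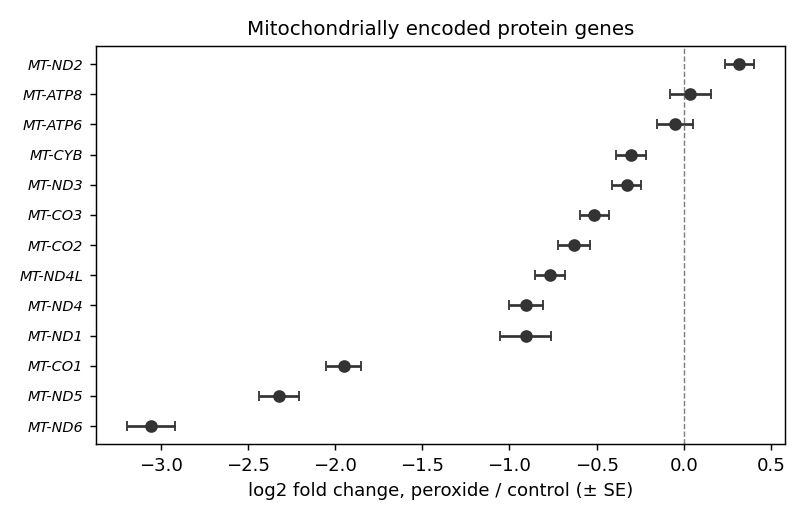
Log2 fold change of peroxide over control (horizontal, ± SE, 8 libraries per group) for the 13 mitochondrially encoded protein genes. Values run from -3.05 for MT-ND6 to 0.32 for MT-ND2.

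Ribosomal protein genes and translation factors rose. Of 74 cytosolic ribosomal protein genes 70 rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 0.39. RPL12 went from 217.2 ± 25.9 to 360.9 ± 58.2 CPM and RPS12 from 412.0 ± 29.2 to 630.4 ± 66.7 CPM. RPS3A and RPS27 had the largest folds among the examples (1.10 ± 0.09 and 1.02 ± 0.11) but under 25 CPM. These genes have near-identical copies, and reads not aligned uniquely are not counted. By camera the list was higher (Benjamini-Hochberg adjusted p = 1.61e-14; adjusted p = 0.336 with an estimated correlation). Translation factors rose in 20 of 29 cases with 0 lower (20 and 0 adjusted over the list alone), with the smallest p-values for EIF1 (1.24 ± 0.10), EIF5 (0.89 ± 0.07), TPT1 (0.63 ± 0.05) and EIF4G2 (0.56 ± 0.05). This list passed camera both ways (Benjamini-Hochberg adjusted p = 4.25e-06; adjusted p = 0.00581 with an estimated correlation).

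Metabolic genes moved in several directions. Cholesterol synthesis genes rose in 14 of 24 cases with 0 lower (15 and 0 adjusted over the list alone). IDI1 rose by 1.90 ± 0.15, HMGCS1 by 1.02 ± 0.23, HSD17B7 by 0.97 ± 0.11 and TM7SF2 by 0.52 ± 0.08. By camera the list was higher (Benjamini-Hochberg adjusted p = 0.00616; adjusted p = 0.631 with an estimated correlation), a call that was lost without a batch term. Fatty acid synthesis genes were not called (adjusted p = 0.528, camera with Benjamini-Hochberg adjustment), with 2 of 15 lower, GPAM at -0.70 ± 0.09 and ACACA at -0.39 ± 0.08, and 0 higher, over all genes and adjusted over the list alone. Hypoxia and glycolysis genes rose in 16 of 33 cases, and HK1, EGLN3 and BHLHE40 fell (16 and 3 adjusted over the list alone), with NDRG1 at 1.42 ± 0.10, KDM3A at 1.01 ± 0.07, PFKFB3 at 0.97 ± 0.08 and the glucose transporter SLC2A1 at 0.77 ± 0.06. Their call (camera, Benjamini-Hochberg adjusted p = 0.0112; adjusted p = 0.554 with an estimated correlation) was lost in batch 1 alone. TXNIP and ARRDC4, related arrestin-domain genes induced by glucose, fell by 1.76 and 1.48. GAPDH rose by 0.24 ± 0.06, a call that was lost in batch 1 alone and without a batch term, and MYC fell by 0.68. HMGCS1 lost its call in batch 2 alone and without a batch term, and ACACA without a batch term.

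Apoptosis regulators went both ways. Of 31 members 10 rose and 9 fell (11 and 9 adjusted over the list alone), and the list was not called (adjusted p = 0.178, camera with Benjamini-Hochberg adjustment). The cell cycle inhibitor CDKN1A rose by 3.73 ± 0.21 on the log2 scale. In the list of FOXO and growth factor withdrawal genes 10 of 24 rose and 8 fell (10 and 8 adjusted over the list alone), with BCL6 at 2.47 ± 0.18, IRS2 at 1.65 ± 0.10, BCL2L11 at 1.33 ± 0.08 and FOXO4 at 0.95 ± 0.08. TXNIP, ARRDC4 and S1PR1 were among the 8 that fell. Its call (camera, Benjamini-Hochberg adjusted p = 0.0150; adjusted p = 0.381 with an estimated correlation) was lost with limma-voom, without a filter and in batch 2 alone. MCL1, which opposes apoptosis, rose by 1.84 ± 0.10.

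Some T cell receptor signalling components fell. In this list 12 of 30 genes fell and BCL10 and MALT1 rose (12 and 2 adjusted over the list alone), with a median log2 fold change of -0.12. The adaptor LAT fell from 11.2 ± 1.49 to 3.98 ± 0.885 CPM, GRAP2 fell by 0.43 and the kinase PRKCQ fell by 0.35 on the log2 scale, and BCL10 rose by 0.50 ± 0.08. By camera the list was lower (Benjamini-Hochberg adjusted p = 0.0229; adjusted p = 0.324 with an estimated correlation). S1PR1, a receptor for lymphocyte egress, fell by 1.59, DGAT2 by 1.79 and LHX4 by 1.62. The long RNAs MIR142HG, MIR29B2CHG and MIR223HG stood at -2.37 ± 0.13, -2.20 ± 0.16 and -1.96 ± 0.16. MTCO1P12, a nuclear copy of MT-CO1, fell by 1.87. T cell activation genes were not called (adjusted p = 0.709, camera with Benjamini-Hochberg adjustment), with 3 of 14 higher and 3 lower, over all genes and adjusted over the list alone. NR4A1, LAG3 and EGR3 rose by 2.82 ± 0.31, 2.75 ± 0.31 and 2.32 ± 0.62, and NFATC1, CD40LG and CD28 fell. EGR3 rose by 5.18 ± 0.86 in batch 1 and 0.92 ± 0.59 in batch 2, and lost its call in batch 2 alone. The activation marker CD69 differed by 0.02 ± 0.33 and did not pass. Its estimates were 0.81 ± 0.43 in batch 1 and -0.69 ± 0.40 in batch 2, and it was called higher in batch 1 alone. Its level was 89.8 and 45.7 CPM in controls 6 and 7, but 15.8 and 14.5 CPM in controls 5 and 8. The peroxide libraries of batch 2 held 19.6 to 33.5 CPM, so the fall there rests on controls 6 and 7. EGR3 and EGR1 were also higher in controls 6 and 7 than in controls 5 and 8. The batch 2 values of these genes thus include differences between single controls.

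The list named for nuclear-retained long RNAs rose in 7 of 13 cases, and NEAT1 and OIP5-AS1 fell (8 and 3 adjusted over the list alone). Those with the smallest p-values were host genes of small nucleolar RNAs, SNHG12 (3.36 ± 0.19), SNHG5 (1.40 ± 0.11) and GAS5 (1.16 ± 0.10), and KCNQ1OT1 (1.87 ± 0.16). NEAT1, the scaffold RNA of paraspeckles, fell by 1.09 and MALAT1 stood at 0.06 ± 0.14; both were chosen after their values were seen. The call (camera, Benjamini-Hochberg adjusted p = 0.00384; adjusted p = 0.369 with an estimated correlation) was lost in batch 2 alone.

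Of 6 tested B cell markers 1, CR2, fell by 0.41, a call that was lost in either batch alone and without control 3 (adjusted p = 0.0645, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 0 passed adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.569). FN1, SPARC, THY1 and COL1A1, the tested fibroblast and epithelial markers, did not pass, and no erythroid marker reached the filter. Of 15 myeloid markers 3 were tested and all 3 rose, ITGAM from 0.161 ± 0.196 to 4.32 ± 2.28 CPM, CD14 from 0.267 ± 0.194 to 3.15 ± 1.10 CPM and CEBPA from 2.58 ± 1.08 to 5.52 ± 2.59 CPM, the last without a call in batch 1 alone. Controls held at most 0.550 CPM of ITGAM and 0.581 CPM of CD14, so both reached the filter through the treated libraries. Among tested members these genes could only rise, and their count says nothing about the list. The myeloid list as a whole held 0.000509% of reads in controls and 0.00179% after peroxide.

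The response was compared between the batches, whose controls differed. Genes of the ATF4 and amino acid response rose by a median of 1.16 in batch 1 and 0.28 in batch 2 on the log2 scale. CHAC1, a glutathione-degrading enzyme, went from 13.2 ± 9.40 to 162.3 ± 24.7 CPM in batch 1 and stood at 159.6 ± 55.2 and 154.5 ± 36.6 CPM in batch 2 (SD, n = 4 each). SESN2, an inhibitor of MTOR signalling, went from 16.7 to 119.7 CPM in batch 1 and from 146.2 to 210.7 CPM in batch 2. HSPA5 had the opposite order, with log2 fold changes of 3.12 in batch 1 and 5.22 in batch 2. Its controls held 466.2 ± 118 CPM in batch 1 and 122.0 ± 15.6 CPM in batch 2. Its peroxide libraries held 4042 ± 721 and 4534 ± 2042 CPM, so the larger fold in batch 2 went mostly with a lower control level. With edgeR's quasi-likelihood test of the interaction and Benjamini-Hochberg adjustment, 688 genes differed in response, 425 with a lower and 263 with a higher log2 fold change in batch 2. DDIT3, ATF3, SESN2, the cystine transporter SLC7A11 and its antisense RNA SLC7A11-AS1 had the smallest interaction p-values, and all 5 responded less in batch 2; without strand the last cannot be told from overlapping transcripts. Camera on the interaction, chosen after the data were examined, placed 5 of 38 lists lower and 9 higher in batch 2, and with an estimated correlation 2 lower (the ATF4 list and nuclear-retained long RNAs) and 0 higher. It placed the ATF4 list lower in batch 2 (Benjamini-Hochberg adjusted p = 8.70e-52; adjusted p = 0.000662 with an estimated correlation). ER chaperones were placed higher in batch 2 (Benjamini-Hochberg adjusted p = 9.79e-06; adjusted p = 0.683 with an estimated correlation). Leaving out single libraries gave 333 (peroxide 5) to 1229 (peroxide 2) interaction genes, with 449, 374, 395, 431 and 406 without control 1, 4, 5, 6 and 8 and 425 without peroxide 4.

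**Figure D4:**
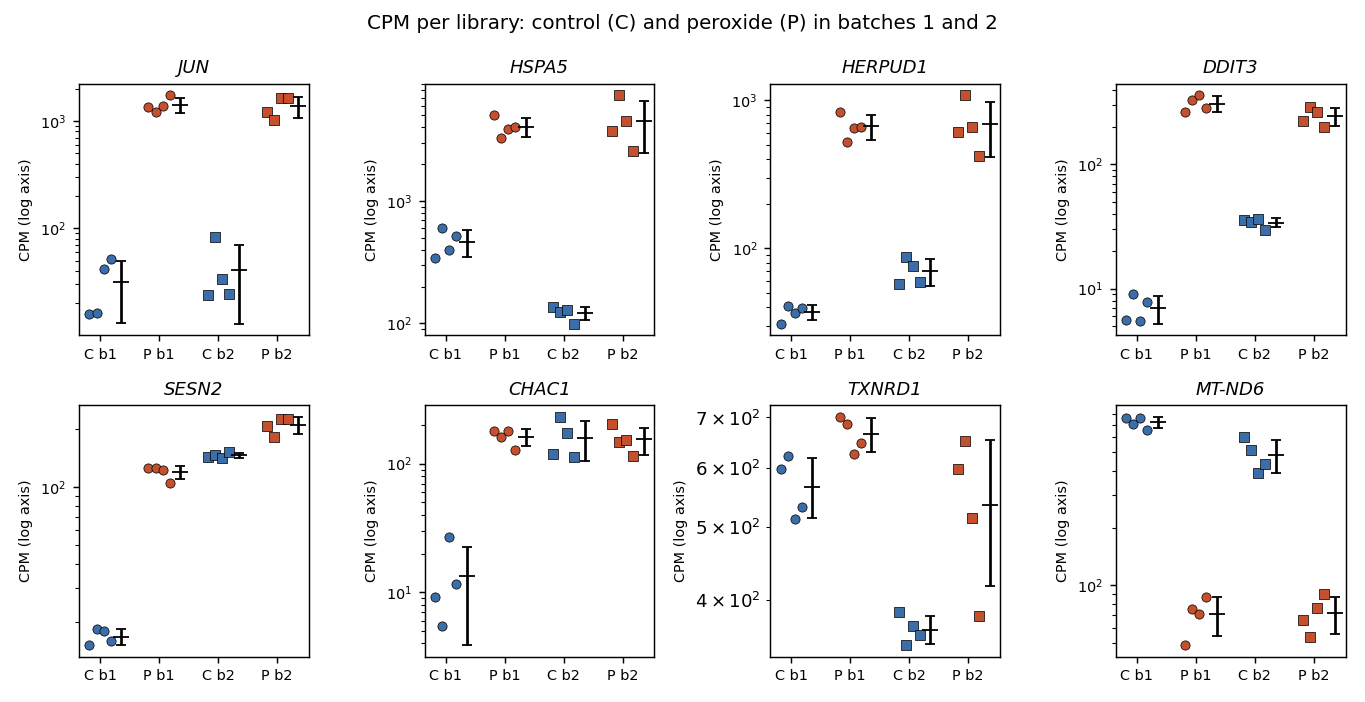
CPM of 8 genes per library on log axes, for control (C, blue) and peroxide (P, red) libraries of batch 1 (b1, circles) and batch 2 (b2, squares), with mean ± SD of 4 libraries as black bars. CHAC1 averages 13.2 CPM in batch 1 controls and 159.6 CPM in batch 2 controls, while its peroxide libraries average 162.3 and 154.5 CPM.

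Most of the response was shared. Fitted alone, batch 1 gave 2858 genes higher and 2410 lower and batch 2 gave 2800 and 2752. Over 13693 genes tested in both, 1748 were higher in both batches, against 536.9 for independent lists, and 1367 were lower in both, against 471.1. Another 41 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of the batches correlated with Pearson's r = 0.863 and Spearman's rho = 0.692.

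**Figure D5:**
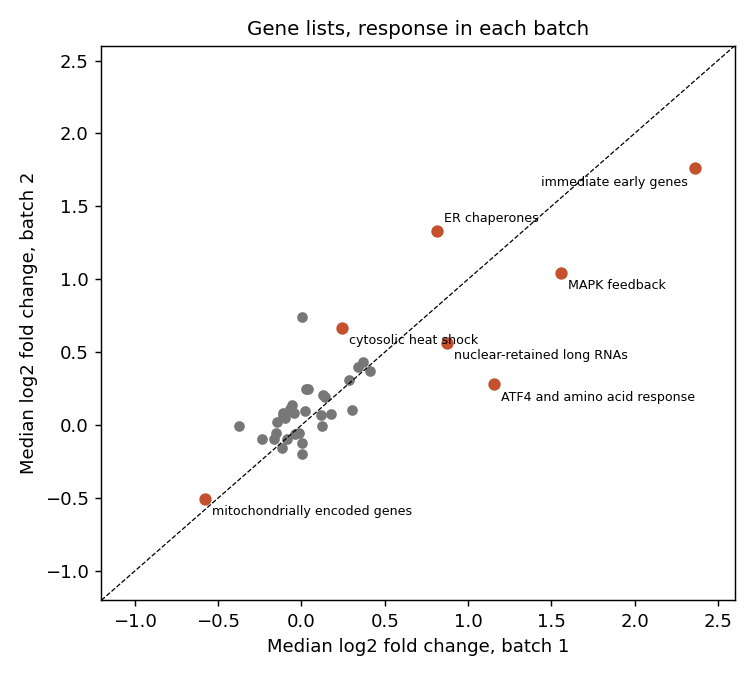
Median log2 fold change of each of the 38 tested gene lists in batch 1 (horizontal) against batch 2 (vertical), with the line of equal response dashed and some lists named. The ATF4 and amino acid response lies at 1.16 and 0.28, and ER chaperones at 0.81 and 1.33.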

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

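The tests of an overall weaker response and of the control level in the ATF4 pattern, and the random splits with the batch kept as a term, were chosen after the result was seen.

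Genes of the ATF4 and amino acid response differed between the batches: the difference in log2 fold change, batch 2 minus batch 1, was -2.69 for DDIT3, -2.32 for SESN2, -2.67 for ATF3, -3.19 for SLC7A11 and -3.70 for SLC7A11-AS1, among 688 genes with a called interaction. ER chaperones had a median difference of 0.45 (95% bootstrap interval over genes 0.28 to 0.80), so this list did not respond less in batch 2. The list cannot speak for the response as a whole, and its interaction had an adjusted p = 0.683 (camera, estimated correlation). Immediate early genes had medians of 2.36 in batch 1 and 1.77 in batch 2, and 1127 and 783 genes rose at least 2-fold. At the preset correlation camera placed 5 lists lower and 9 higher in batch 2. A weaker response of batch 2 as a whole therefore stays open. Scaling is argued against, since the ATF4 list's median difference of -0.83 came no closer to 0 than -0.81 under the other scalings. A candidate explanation is a response already under way in the batch 2 controls. They lay above the batch 1 controls by a median of 1.35 (95% bootstrap interval over genes 1.25 to 2.25), while the peroxide libraries differed by 0.53 (0.27 to 0.78). These intervals leave out the spread among libraries. Both differences make up the difference in response, so they describe the pattern and do not test its cause. Other lists differed the other way between the controls, with batch 2 minus batch 1 medians of -1.36 for cytosolic heat shock, -0.96 for cholesterol synthesis and -0.36 for ER chaperones. The larger fold of the ER chaperones in batch 2 thus includes a lower control level and is no measure of a stronger response. What moved the controls apart was not tested, and a difference in culture or handling between batches stays open.

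Random regroupings give a measure of chance for the interaction. Of 100 splits of each group into 4 and 4 libraries, the real one included and the batch kept as a term beside the split, 1 gave as many interaction genes as the real 688. The highest other gave 443, and it differed from the batches by the exchange of 1 peroxide library of each batch. Random splits thus rarely reached the real count. Any difference in response between the batches adds to the spread in the other splits, however, and lowers their counts, so the share is not taken to exclude chance. The splits were first fitted without the batch term, where 3111 genes were called for a split that mostly crossed the batches between the groups, which points to the batch effect as a structure of the samples.

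Single libraries stood apart from the other 7 of their group in 9 of 370 series of a named gene's log2 CPM in a group, where chance alone gives about 1 in 20, or 18.5. That rate assumes values from a single normal distribution. Each series pooled both batches, which can widen its range and hide outliers, so 9 does not mean fewer than chance. IQCN was at 0.563 CPM in control 2, against a median of 1.83 in the others, LHX4 at 8.95 CPM in control 3, against 12.1, GCLC at 99.2 CPM in control 1, against 76.6, and TCF7L1, a Wnt transcription factor, at 0.166 CPM in control 1, against 0.773. CAT was at 95.8 CPM in peroxide 2, against 78.1, and BCL10 at 33.7 CPM in peroxide 1, against 25.4. In peroxide 6, EGR1 was at 130.4 CPM, against 361.9, MYC at 111.2 CPM, against 175.4, and MAP1LC3B, an autophagy gene, at 114.7 CPM, against 87.6.

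Control 1 also stood apart in its reads without a gene. Reads not aligned uniquely were 47.2% of its counted reads, against a median of 32.2% in the other controls, and ambiguous reads were 3.70%, against 4.81%. Both are shares of the same counted reads, so the low ambiguous share follows from the high share not aligned uniquely and is not a separate departure.

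The reads outside genes differed between the batches. The share of reads in no gene rose from 7.65% ± 0.728 to 9.58% ± 0.823 in batch 1 and fell from 8.56% ± 0.322 to 7.37% ± 0.530 in batch 2 (SD, n = 4 each). The difference between the batches was -3.13 percentage points (exact permutation of batches within groups, p = 0.00122, two-sided). The share not aligned uniquely was 7.97 percentage points higher after peroxide in batch 2 (exact permutation p = 0.0286, two-sided, the smallest possible with n = 4 each), and 0.561 points higher in batch 1 (exact permutation p = 0.943). Both are shares of the same counted reads, so more reads not aligned uniquely leave a smaller share in no gene. The fall in batch 2, and the part of the -3.13 points that it makes up, is therefore not a result separate from that rise.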

How the results depend on the processing

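Leaving out together the 2 libraries with the largest share of reads not aligned uniquely, and the list tests of the interaction, were chosen after the data were examined; that omission gave 3157 genes higher and 3199 lower, and 850 and 141 at 2-fold. The counts of genes higher and lower stayed within 1.5 times the main values except that 5150 genes were higher without a filter, where more genes are tested. The 2-fold counts followed the genes tested, with 3076 higher and 486 lower without a filter and 387 and 53 at a mean of 5 CPM. DESeq2, run without a filter, gave 2452 and 312, and summing libraries of the same number gave 1401 and 221; the cause was not tested. With total counts the median log2 fold change of all genes was -0.08 in place of -0.01. With an estimated correlation 2 lists were higher (MAPK feedback and translation factors) and 0 lower, the lists lower numbered 6 without a filter, and leaving out mitochondrially encoded genes left 1 because that list could not be tested. The interaction gave 1157 genes with DESeq2, the cause not tested. Leaving out 1 library gave 3189 to 3438 genes higher, 3221 to 3604 lower, 818 to 951 and 131 to 156 at 2-fold, and 13 to 15 lists higher; for the interaction it gave 333 genes without peroxide 5, 374 without control 4, 395 without control 5, 406 without control 8, 425 without peroxide 4, 431 without control 6, 449 without control 1 and 1229 without peroxide 2. CHAC1 reversed to -0.054 in batch 2 alone, where it did not pass. Without a batch term TXNRD1, CHAC1, TRIB3, HMGCS1, EGR1, GAPDH, SOD1, PRDX4, DNAJA1, ACACA, CKS2, H2BC5, LEF1, CR2 and SESN2 lost their calls. EGR1 lost its call without control 1, 4 or 5 or peroxide 4 or 8 (adjusted p 0.0505 to 0.0725). The nuclear respiratory chain lost its call without control 5, 6, 7 or 8 or peroxide 5 or 8 (adjusted p 0.0582 to 0.0859). Without leaving out a library, 38 results for named genes and 26 for lists lost their call, and 8 and 10 gained one. Another 2629 and 493 kept their side of the threshold, and a change of direction was not counted where neither fit passed. Leaving out 1 library, 10 and 6 lost the call, 3 and 1 gained one, and 3139 and 601 kept their side. The fit with the replicate number as a block gave 3313 genes higher and 3374 lower, and changed no call of a named gene or list; equal numbers did not mark paired libraries, as 3 of 8 pairs had a correlation of deviations over 0.1 (range -0.22 to 0.30) and 3 of 8 correlated best with their own number in their batch. In simulated counts, 52.0% of changes of 1.25-fold were recovered with 8 against 8, for genes with a mean of 5 CPM or more.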

Other observations

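The tests of mitochondrial genes were chosen after the result was seen, and the test of single nuclear copies was chosen after a first test on all copies had left that explanation undecided. The comparison of the count of lists lower with the smaller direction of each random split was also chosen after the result was seen. The tests of neighbouring genes, of counting noise and of the other counts over random splits were fixed before their results were seen.

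Signalling lists that were not called by camera held members with large changes. In JAK-STAT signalling SOCS1, a feedback inhibitor, rose by 2.84 ± 0.26 and the kinase PIM2 by 1.94 ± 0.10, with 9 of 30 members higher and 7 lower (9 and 8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.104). In the list of TGF-beta, BMP and SMAD signalling ID2 rose from 8.66 to 73.3 CPM, while TGFBR2 and PMEPA1 fell by 0.67 and 0.64, with 8 of 25 higher and 7 lower (8 and 8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.925), and the list's median of -0.10 differed in sign from its mean of 0.25 and its test. Of 28 genes of PI3K, AKT and MTOR signalling 13 fell and 4 rose (13 and 4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.177, under 0.05 without a filter), with RPTOR at -0.57 ± 0.06, PIK3R1 at -0.66 ± 0.08, PIK3CG at -0.68 ± 0.09 and SGK1 at 2.91 ± 0.20. Among Notch targets HES1 and NRARP rose by 1.78 ± 0.16 and 3.20 ± 0.22 and NOTCH3 fell by 0.96, with 3 of 15 higher and 5 lower (3 and 6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.668), a median of -0.12 and a mean of 0.16. IRF7 rose by 1.62 ± 0.12 while IFIT5 fell by 0.71 among 30 interferon-stimulated genes, of which 5 rose and 8 fell (5 and 7 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.599). PRKDC and BRCA1 of the DNA repair list fell by 0.71 and 0.40, and its repair glycosylase NEIL1 rose by 1.22 ± 0.13, with 11 of 32 lower and 4 higher, over all genes and adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.248, under 0.05 without a filter and in batch 2 alone).

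Many genes that rose at least 2-fold lie just downstream of an expressed gene. IQCN lies downstream of JUND on the same strand, and TUBB3, DDIT3, SNHG12, CD14, NR4A1, LAG3, PHLDA1, PIM2, NEIL1 and ATF4 also have such neighbours, but of the 15 largest rises only 2 do (IQCN and TUBB3). After peroxide ATF4 (1130 CPM), SNHG12 (275.4 CPM), NR4A1 (93.7 CPM) and DDIT3 (276.5 CPM) lay above their upstream neighbours MIEF1 (80.3 CPM), TAF12 (37.7 CPM), TAMALIN (19.8 CPM) and DCTN2 (159.2 CPM), neighbours named after their values were seen, so reads running on from these would not readily account for them. Chosen after their values were seen, FGF18 lies downstream of NPM1, APOE downstream of TOMM40 and IL13 downstream of RAD50, and they rose by 4.58 ± 0.31, 4.05 ± 0.24 and 4.23 ± 0.29 on the log2 scale. RAD50 stood at -0.16 ± 0.12, which did not pass, TOMM40 rose by 0.21 ± 0.08 and NPM1 by 0.64 ± 0.07.

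A hypothesis for part of the rises is transcription that runs on past the end of the upstream gene. Of the 836 genes, 820 had a position in the annotation and 29.6% of them had an upstream expressed neighbour within 10 kb, against 13.7% of expression-matched genes that did not pass (permutation p = 1e-04, the smallest that 10000 draws give), an excess of 15.9 percentage points. Gene-dense regions or regulation shared with neighbours on either side are argued against, since the excess for downstream neighbours was 1.99 points and the difference of 13.9 points had a 95% bootstrap interval of 9.15 to 18.7. Counting noise is argued against for genes tested in both batches. Of 985 of these at least 2-fold higher in batch 1 alone, 88.0% were higher in batch 2, against 19.9% of all genes tested in both. In the reverse direction it was 94.7% of 717, against 19.8%. Batch 1 alone gave 1127 genes at least 2-fold higher and batch 2 alone 783. Those that missed the filter of the other batch, where levels were low, are not covered. Read positions, which would test the hypothesis directly, were not analysed here, most of the 836 genes have no such neighbour, and strand and build stay open.

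For the fall of mitochondrially encoded transcripts, a change of scaling or of mitochondrial RNA content that moves all genes alike is argued against as the whole account by the range of 3.37 between MT-ND6 (-3.05 ± 0.14) and MT-ND2 (0.32 ± 0.08). The range cannot exclude a common fall beneath uneven changes, as 10 of 13 protein genes fell and 1 rose. For reads lost to nuclear copies, the median change of all 4 tested copies, -0.45 (95% bootstrap interval -1.87 to 0.19), left the matter undecided. MTCO1P12 fell by 1.87 and MTND4P12 (chosen after its value was seen) changed by -0.94 ± 0.10, close to MT-CO1 and MT-ND4, which decides nothing because a read that fits a gene and its copy is counted for neither. Loss to copies therefore stays open, as may uneven changes in synthesis or stability and effects of saline, which were not tested.

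Random splits of the 16 libraries into 8 and 8 tested whether groups drawn at random reach the counts of the comparison. Of 100 splits, the real one included, 1 gave as many genes as the 3391 higher or the 3419 lower (highest other 1920, from a split that exchanged 1 library of each group). For genes at least 2-fold higher 1 split reached 836 (highest other 566) and for those at least 2-fold lower 2 reached 129 (highest other 566, counting the larger direction of each split). For gene lists higher, 3 splits reached 14 (highest other 16). Random groupings thus rarely reached these 5 counts. A split that mixes the groups leaves the treatment difference within its parts, however, which lowers its gene counts, so the shares are not taken to exclude chance. Lists were called even in splits with 0 genes called, such as 11 higher and 2 lower in 1 split with 4 controls in each part. For gene lists lower, the smaller direction of each split was compared, and 54 reached 2 (highest other 5), so chance cannot be excluded for that count.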
